A study of Mus musculus with 14 samples.

How the data were processed

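Gene expression was measured by polyadenylated RNA sequencing of ventricular heart tissue from mice, collected 1 week after surgery. The surgery was either transverse aortic constriction (TAC), in which a ligature narrows the aorta so that the left ventricle pumps against a raised pressure, or a sham operation without the constriction. The mice were wild type or lacked Ccl24, the gene of a CC-type chemokine. The labels gave 14 libraries in 4 groups: wild type sham (n = 2, replicates 1 and 2), wild type TAC (n = 6, replicates 1, 2, 3, 4, 6 and 7), knockout sham (n = 2, replicates 1 and 2) and knockout TAC (n = 4, replicates 1, 2, 4 and 5). The number of libraries in each group equalled the number of mice that the study's design text gives, so each library was taken as 1 mouse.

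The authors deposited a table of raw read counts per gene, in whole numbers and without normalization, with 54532 Ensembl gene IDs and their symbols. Per the submitters' processing notes, reads were handled with FastQC, HISAT2 2.1.0, featureCounts and edgeR on the mouse genome build GRCm38. The roles and settings of these tools, the annotation release and whether the counting used strand are not given in the sources used here. Counts of genes that overlap on opposite strands, or that have near-identical copies, are therefore uncertain. Of the gene IDs, 54409 were also in the GENCODE M21 annotation of GRCm38, which was used for coordinates. Among its symbols, 105 belonged to more than 1 ID.

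Total counts were 17072262 to 33123052 per library, and 3 counts in a library stood for 0.091 to 0.18 CPM, the usual unit of counts scaled to the total of a library. Intervals on counts cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries within a group agreed within sampling noise, since the chi-square per degree of freedom of a pair's counts lay between 4.79 and 191, so each library counted as 1 replicate.

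Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the group, which left 15876 genes. Library sizes were scaled with TMM factors, and a model of the 4 group means was fitted over all 14 libraries with glmQLFit (robust), so that all groups shared an estimate of the spread. The quasi-likelihood F test was run for 5 comparisons: TAC against sham in each genotype, knockout against wild type in each surgery, and the genotype by surgery interaction. P-values were adjusted with the Benjamini-Hochberg method over the genes of a comparison, and the threshold was an adjusted p of 0.05. The standard error (SE) of a log2 fold change was taken as its size divided by the square root of F. Levels are CPM with TMM factors, given as mean ± SD.

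A total of 40 gene lists, with 797 distinct genes, covered pathways, cell types and signs of tissue quality. In each comparison 39 of them had enough expressed members to be tested. Lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. Each call was repeated with the correlation estimated from the data and with fry. Camera compares a list with all other genes, and fry asks whether the genes of a list move, on balance, one way. For each list the members past the threshold were counted in 2 ways, adjusted over all genes and adjusted over the list alone. A list score in a library is the mean of log2(CPM + 0.5) over the members of a list, and scores were compared with exact two-sided permutation tests.

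The genes named in the text were taken by a rule. It takes Ccl24, up to 10 higher and 10 lower genes per comparison with the largest change among those past the threshold with a mean of at least 1 CPM in the higher group, up to 4 members with the smallest p of each list described, and a fixed set of 10 genes in every comparison. Where no gene passed, it takes the 3 higher and 3 lower genes with the smallest unadjusted p. The groups, the comparisons, the edgeR, camera and fry tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined. The list scores and their permutation tests were not part of that plan. Genes named outside the rule are marked where they appear. A result for 1 of the genes taken by the rule was left out and is not reported here.

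The steps were tested on simulated counts drawn from the means and library sizes of the real libraries, with 200 genes changed among 15876. Genes were drawn independently, each with the same dispersion in all libraries. Unequal spread between libraries (voom sample weights of 0.288 to 2.21) and links between genes were therefore left out, and the rates hold for that simpler setting. In TAC against sham in wild type 25.8% of genes changed 1.5-fold and 63.1% of genes changed 2-fold were recovered, and in TAC against sham in knockout 17.6% and 53.2%. In knockout against wild type the recovery of 1.5-fold and 2-fold changes was 45.7% and 76.4% after TAC and 10.7% and 49.3% after sham surgery. For the interaction 2.86% of 1.5-fold, 42% of 2-fold and 80.3% of 4-fold differences were recovered. False calls were 4.07% to 6.8% of the calls of a comparison, highest for TAC against sham in knockout. A random list left unchanged had an unadjusted camera p of 0.0381 in TAC against sham in wild type. In the other comparisons that p was 0.0539 to 0.587.

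The alternatives were other normalizations (RLE and upper quartile), no filter and a stricter filter of 1 CPM in 4 libraries, glmQLFit without robust estimation, fits with the 2 compared groups alone, mitochondrial and haemoglobin genes removed, the replicate number as a block, DESeq2 1.42.0, limma 3.58.1 voom with quality weights, and leaving out each library in turn.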

Results

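The series compared the hearts of mice lacking the chemokine gene Ccl24 with wild type hearts, 1 week after TAC or sham surgery, in a study of cardiac fibrosis. The 14 libraries held 17072262 to 33123052 gene counts each. Mean totals were 21810000 ± 2673000 in wild type sham (SD, n = 2), 25190000 ± 4657000 in wild type TAC (n = 6), 21370000 ± 1467000 in knockout sham (n = 2) and 22780000 ± 4236000 in knockout TAC (n = 4). Mitochondrially encoded genes took 18.6% ± 0.212 of the counts in wild type sham (SD, n = 2), 13.9% ± 2.79 in wild type TAC (n = 6), 22.1% ± 2.26 in knockout sham (n = 2) and 16.5% ± 1.92 in knockout TAC (n = 4).

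Ccl24 lies on chromosome 5 at 135569937 to 135573049 on the minus strand of GRCm38. All 6 knockout libraries held 3 to 8 Ccl24 counts. The wild type sham libraries held 61 and 72 counts, and wild type TAC replicates 2, 3, 4, 6 and 7 held 105, 56, 100, 69 and 94. The library labelled wild type TAC replicate 1 held 3 counts (exact 95% Poisson interval 0.619 to 8.77), which is at the level of the knockout libraries and goes against its label. It was kept in its labelled group, and every comparison that uses it was repeated without it. The level was 3.13 ± 0.743 CPM in wild type sham (SD, n = 2), 2.68 ± 1.43 CPM in wild type TAC (n = 6), 0.228 ± 0.114 CPM in knockout sham (n = 2) and 0.243 ± 0.0888 CPM in knockout TAC (n = 4). Without the library labelled wild type TAC replicate 1, the wild type TAC mean was 3.19 ± 0.788 CPM (n = 5).

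**Figure D1:**
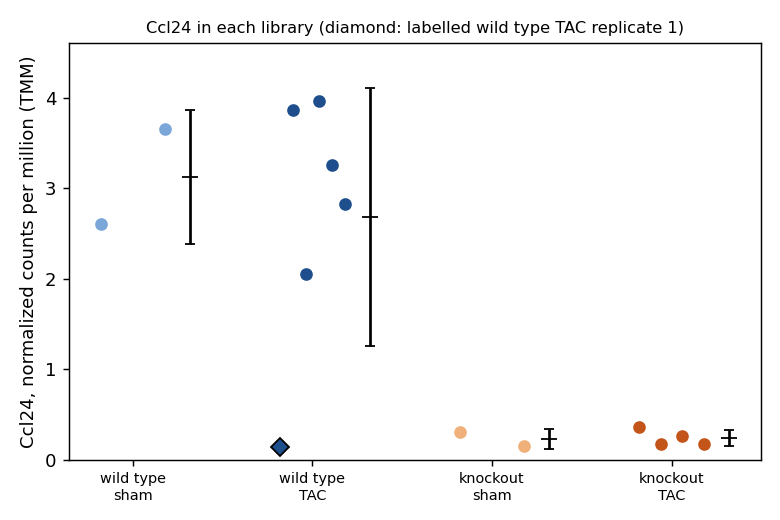
Ccl24 level in CPM (vertical axis) in each library, by group (horizontal axis). Points are libraries, black bars are the mean ± SD of a group, and the diamond is the library labelled wild type TAC replicate 1, which lies with the knockout libraries at 0.143 CPM.

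At 18 other genes that set all knockout libraries apart from all other wild type libraries, chosen after the data were seen, the library labelled wild type TAC replicate 1 lay between the ranges of the genotypes at 13. It lay within or beyond the knockout range at 3 and within or beyond the wild type range at 2. On a scale with the other wild type libraries at 0 and the knockout libraries at 1, its median position was 0.6. Its positions ran from 0.11 (Zhx2) to 1.05 (Cys1 and Zfp979). Knockout libraries left out of the choice of genes in the same way lay at 0.82 to 1.08 and wild type libraries at -0.09 to 0.14. At Zhx2 it held 3.95 CPM, where the knockout libraries held 23.7 ± 2.82 (SD, n = 6) and the other wild type libraries 1.53 ± 0.366 (n = 7). At Arl2bp it held 54.9 CPM, against 27.1 ± 3.33 and 84 ± 3.23.

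**Figure D2:**
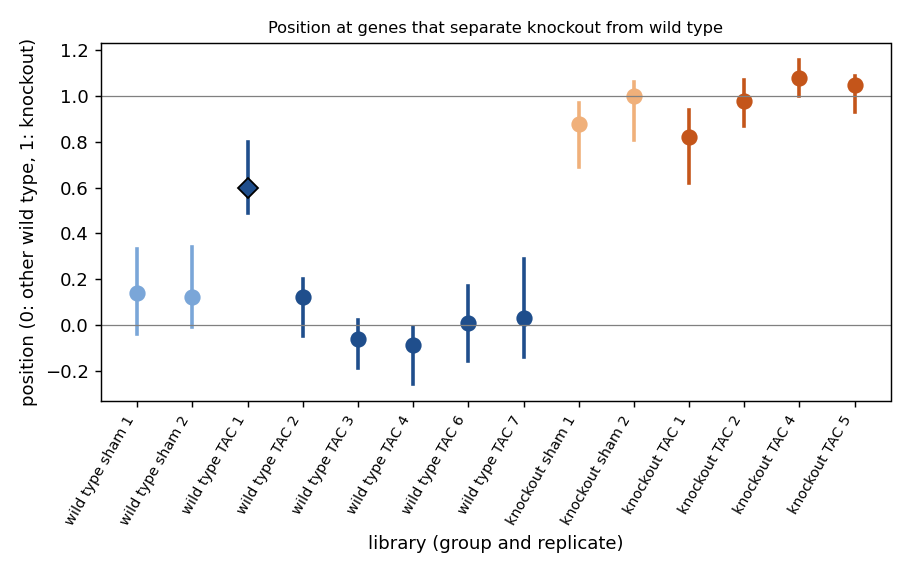
Position of each library (horizontal axis) between the other wild type libraries (0) and the knockout libraries (1) at genes that separate the genotypes, each library being left out when the genes were chosen. Points are medians over genes and lines run from the lower to the upper quartile (vertical axis, no unit); the diamond, the library labelled wild type TAC replicate 1, lies at 0.6.

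Between the genotypes Ccl24 was lower in the knockout after TAC, with a log2 fold change of -3.44 (SE 0.65, adjusted p = 0.0091), and of -3.69 (adjusted p = 5.4e-06) without the library labelled wild type TAC replicate 1. After sham surgery the difference was -3.76 (SE 0.99) and did not pass (adjusted p = 0.2), although it passed without that library (adjusted p = 0.002). TAC did not measurably change Ccl24 in wild type, at -0.21 (SE 0.59, adjusted p = 0.84) with that library and 0.03 (adjusted p = 0.95) without it, or in the knockout, at 0.1 (SE 1.13, adjusted p = 0.97). Ccr3, the gene of the receptor for this chemokine, was among the 16 members of the eosinophil list that fell below the expression filter; it held 7 counts over all 14 libraries and was not tested.

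The first principal component of the 1000 most variable genes held 44.9% of the variance and the second 18.6%. The sham libraries of both genotypes lay at the low end of the first component. On the second, the knockout TAC libraries lay below the wild type TAC libraries, and the library labelled wild type TAC replicate 1 was the wild type TAC library nearest to them. The knockout sham libraries (5.4 and 1.2) also lay below the wild type sham libraries (18.5 and 20.6) on the second. On the first, knockout sham lay at -34 and -33.4 and wild type sham at -17.1 and -20.6.

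**Figure D3:**
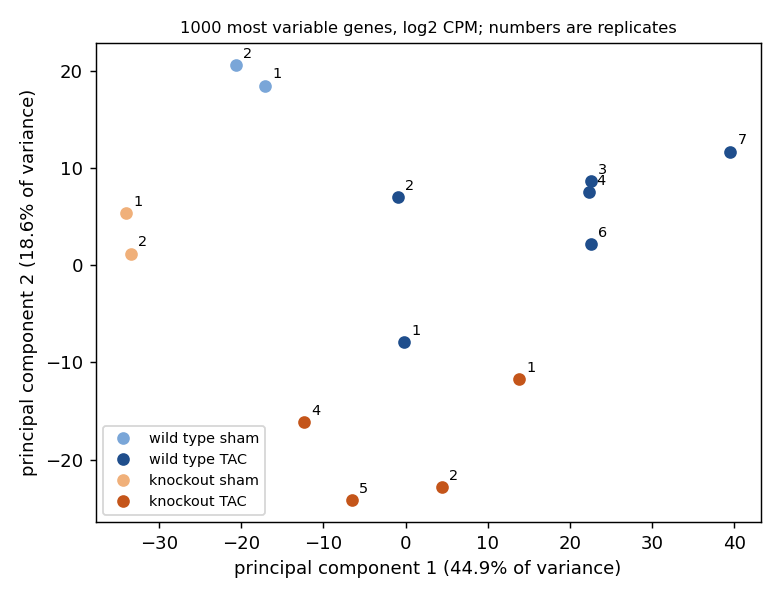
Principal components 1 (horizontal axis, 44.9% of variance) and 2 (vertical axis, 18.6%) of the 1000 most variable genes in 14 libraries. Each point is a library, its color gives the group, and its number is the replicate.

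TAC against sham in wild type hearts asked what pressure overload did 1 week after surgery. Of the 39 extracellular matrix genes tested, 24 rose. The fibrillar collagen genes Col1a1 (log2 fold change 2.01, SE 0.58, adjusted p = 0.044) and Col3a1 (2.05, SE 0.5, adjusted p = 0.025) went up about 4-fold. Col1a1 went from 267 ± 37.4 CPM (SD, n = 2) to 1080 ± 634 CPM (n = 6). Postn, which codes for the matrix protein periostin made by activated fibroblasts, rose from 206 ± 39.7 CPM (n = 2) to 1200 ± 717 CPM (n = 6; adjusted p = 0.041). Past the threshold were also increases in 23 of 31 cell cycle and 15 of 23 pan-macrophage genes, and decreases in 13 of 27 genes of contraction and ion handling and 8 of 30 of fatty acid oxidation. None of the camera calls of these 5 lists was kept with an estimated correlation (adjusted p = 0.31 for each).

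The 24 matrix genes that passed included Lum (1.22, SE 0.22), Col6a2 (1.23, SE 0.22) and Fbn1, the gene of fibrillin (1.93, SE 0.36). The other 15 did not pass, and 38 rose when adjusted over the list alone. The median was 1.75 (camera adjusted p = 2.1e-21; adjusted p = 0.31 with an estimated correlation). Among 31 cell cycle genes 23 rose (29 adjusted over the list alone), with a median of 1.52, led by Cdk1 (2.36, SE 0.39), the kinase that drives entry into mitosis, and the cyclin gene Ccnb1 (2.74, SE 0.5). That call had a camera adjusted p of 6.5e-22 and an adjusted p = 0.31 with an estimated correlation. Among 23 pan-macrophage genes 15 rose (18 adjusted over the list alone), with a median of 0.85. They included Cd68 (0.85, SE 0.18), Mpeg1 (1.35, SE 0.28), the complement gene C1qa (0.79, SE 0.17) and Adgre1, which codes for the macrophage surface protein F4/80 (0.89, SE 0.23). Its camera adjusted p was 7e-12, with an adjusted p = 0.31 with an estimated correlation.

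Of 25 load-induced cardiomyocyte genes 8 rose and 17 did not pass (18 rose adjusted over the list alone; median 1.13). They included Acta1, the skeletal actin gene that loaded heart muscle re-expresses (1.13, SE 0.24), and Nppb, the gene of B-type natriuretic peptide (1.15, SE 0.26). Camera gave an adjusted p of 2.6e-08 for them, and an adjusted p = 0.31 with an estimated correlation. Nppa, at 2.22 (SE 0.7, adjusted p = 0.062), Myh7, at 0.42 (SE 0.22, adjusted p = 0.2), and Myh6, at -0.35 (SE 0.17, adjusted p = 0.18), did not pass. Among 27 genes of adult cardiomyocyte contraction and ion handling 13 fell (13 adjusted over the list alone; median -0.35), among them Atp2a2, the calcium pump of the sarcoplasmic reticulum (-0.88, SE 0.2), and the potassium channel gene Kcnj2 (-1.19, SE 0.17). Among 30 fatty acid oxidation genes 8 fell (17 without the library labelled wild type TAC replicate 1; 12 adjusted over the list alone; median -0.52), led by Ppara (-1.65, SE 0.24) and Ppargc1a (-0.93, SE 0.14), which code for a nuclear receptor and a coactivator of this pathway. Camera called both lists, with adjusted p of 2e-07 and 1e-11, and neither was called with an estimated correlation (adjusted p = 0.31 for each).

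In all, edgeR called 1930 genes, 1009 higher and 921 lower after TAC, of which 320 and 122 had changed at least 2-fold. Limma voom called 2822 higher and 2908 lower and RLE scaling gave 950 and 986, so the side with more genes depended on the method. Among genes with a mean of at least 1 CPM in the higher group, the largest increases were in Pclaf (3.64, SE 0.63), which acts in DNA replication, Ereg (3.48, SE 0.99) and Tnc (3.46, SE 0.97), the gene of the matrix protein tenascin C. The call of Ereg was lost without knockout TAC replicate 5 or wild type TAC replicate 4, among other libraries. Cngb3 (-2.24, SE 0.43), Lgi1 (-1.93, SE 0.35) and Ano5 (-1.84, SE 0.35) were among the genes with the largest decreases. The count rested on both sham libraries, since it was 4 without wild type sham replicate 1 and 0 without replicate 2, and it was 1256 without wild type TAC replicate 4. The calls of Col1a1, Postn and Tnc were each lost in 9 of the 14 fits that left out a library, namely without knockout sham replicate 1 or 2, knockout TAC replicate 2 or 5, wild type sham replicate 1 or 2 or wild type TAC replicate 3, 4 or 6, where the adjusted p of Col1a1 was 0.056 to 0.3. Without the library labelled wild type TAC replicate 1 it was 2756, including 1903 of the 1930 genes.

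TAC against sham in knockout hearts asked the same of mice without Ccl24. Cell cycle genes rose most widely, with 29 of 31 past the threshold (30 adjusted over the list alone) and a median of 2.12, and examples were Tpx2 (2.9, SE 0.36), Cdk1 (2.66, SE 0.38) and Prc1 (3.12, SE 0.45). Camera gave that list an adjusted p of 1.1e-49, and an adjusted p = 0.087 with an estimated correlation. Acta1 rose from 3800 ± 230 CPM (SD, n = 2) to 13000 ± 2800 CPM (n = 4), and Nppb from 347 ± 66.1 CPM (n = 2) to 980 ± 206 CPM (n = 4). Ankrd1, a stress-responsive sarcomere gene, rose by 1.38 (SE 0.19, adjusted p = 0.003). Of 25 load-induced genes 6 rose and 19 did not pass (18 rose adjusted over the list alone; median 1.38; camera adjusted p = 1.6e-16; adjusted p = 0.12 with an estimated correlation).

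Of 39 matrix genes 3 rose and 36 did not pass, while 26 rose and 1 fell adjusted over the list alone. Without the library labelled wild type TAC replicate 1 the number that rose was 8. The 3 were Vcan (1.39, SE 0.31), Col6a2 (0.97, SE 0.23) and Loxl2, a collagen crosslinking enzyme (1.68, SE 0.38). All of these calls were lost without knockout TAC replicate 2, and those of Col6a2 and Loxl2 also without knockout TAC replicate 1. The list median was 1.23 (camera adjusted p = 2e-15; adjusted p = 0.41 with an estimated correlation). Col1a1, at 1.47 (SE 0.58, adjusted p = 0.17), Col3a1, at 1.37 (SE 0.5, adjusted p = 0.14), and Postn, at 2.8 (SE 0.73, adjusted p = 0.059), did not pass. Among 21 quiescent fibroblast genes 4 fell, namely Htra3 (-0.82, SE 0.18), Fbln1 (-0.73, SE 0.19), Vit (-1.35, SE 0.36) and Scara5 (-1.13, SE 0.29), and 1 rose (3 without the library labelled wild type TAC replicate 1), while 8 fell and 5 rose adjusted over the list alone (camera adjusted p = 0.17). None of 23 pan-macrophage genes passed (1 without the library labelled wild type TAC replicate 1; 0 adjusted over the list alone; median 0.36), although camera called the list at an adjusted p of 0.00062 (adjusted p = 0.59 with an estimated correlation), and Adgre1 stood at 0.21 (SE 0.24, adjusted p = 0.66). Immediate early genes, which are also switched on while tissue is handled, rose at 10 of 26 members (18 adjusted over the list alone; median 0.86), among them Jun (0.87, SE 0.11), Egr3 (2.94, SE 0.37) and Nr4a1 (1.82, SE 0.24). This list was the only list of the 39 in this comparison that camera called with an estimated correlation (adjusted p = 0.041), and without the library labelled wild type TAC replicate 1, which enters through the shared estimate of the spread, that value was 0.076.

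The knockout comparison had 648 called genes, 374 higher and 274 lower, while limma voom called 824 higher and 1074 lower. With the 2 compared groups fitted alone the count was 1458 in knockout and 736 in wild type, so which genotype had more called genes depended on the fit. Under the same limit of 1 CPM the largest increases were in Sgo1 (3.69, SE 0.69) and Ncapg (3.65, SE 0.58), which act in chromosome segregation and condensation. Nmrk2 (3.32, SE 0.66), an enzyme of NAD synthesis, was also among the 10 largest. Clec18a (-2.32, SE 0.57) and Scd4 (-2.18, SE 0.48) were among the genes with large decreases. The count was 1 without knockout sham replicate 1, 183 without knockout sham replicate 2, 200 without knockout TAC replicate 2, 374 without knockout TAC replicate 5 and 1361 without wild type TAC replicate 7. The calls of Htra3, Fbln1, Vit and Scara5 were lost in 3, 8, 9 and 10 of the 14 fits that left out a library, and those of Clec18a and Scd4 in 7 and 4. Without the library labelled wild type TAC replicate 1 it was 842, including 644 of the 648.

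The responses to TAC in the genotypes share no library. Across genes their log2 fold changes correlated with a Pearson r of 0.64 and a Spearman rho of 0.63, a description only since genes are not independent replicates. Among called genes 241 were higher in both genotypes, where independent lists of these sizes would share 23.8, and 164 were lower in both, where 15.9 would be shared. The number called in opposite directions was 1.

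Knockout against wild type after TAC asked how expression differed between the genotypes 1 week after TAC, whatever the levels before it. Of 21 quiescent fibroblast genes 15 were lower in the knockout. Pdgfra, the receptor that marks cardiac fibroblasts, stood at 51.9 ± 4.17 CPM in knockout TAC (SD, n = 4) and 83.8 ± 10.2 CPM in wild type TAC (n = 6), a log2 fold change of -0.69 (SE 0.09, adjusted p = 0.00088). Tcf21, a transcription factor of resident fibroblasts, differed by -0.91 (SE 0.13, adjusted p = 0.0014), and Mmp2, a matrix-degrading protease, by -1.25 (SE 0.21, adjusted p = 0.0055). Past the threshold were also decreases in 5 of 23 pan-macrophage genes, and increases in 15 of 31 cell cycle, 15 of 37 respiratory chain and 11 of 26 immediate early genes. None of the camera calls of these lists was kept with an estimated correlation (adjusted p of 0.058 for quiescent fibroblast genes and 0.41 to 0.44 for the others). These directions were drawn with the library labelled wild type TAC replicate 1 in the wild type group, and all of the genes just named kept their direction and passed without it.

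In the quiescent fibroblast list none was higher (20 lower adjusted over the list alone), with a median of -0.69, and Cd248 (-0.9, SE 0.14) and Dpt (-0.54, SE 0.09) were further examples. Camera gave an adjusted p of 4.3e-18 and an adjusted p = 0.058 with an estimated correlation (adjusted p = 0.032 with an estimated correlation without the library labelled wild type TAC replicate 1). The quiescent fibroblast score was 6.48 ± 0.06 in knockout TAC (SD, n = 4) and 7.15 ± 0.18 in wild type TAC (n = 6). All 4 knockout libraries lay below all 6 wild type libraries (exact two-sided permutation p = 0.0048, the smallest that 210 groupings can give). The score tests in this part were not planned, and their p-values are not adjusted over lists. In wild type this score was 6.77 and 6.8 after sham surgery and 6.87 to 7.33 after TAC. In knockout it was 6.43 and 6.61 after sham surgery and 6.43 to 6.55 after TAC. Every knockout TAC library lay within the range of the knockout sham libraries, so a loss of these cells with TAC is not shown. Of 39 matrix genes 7 were lower and 32 did not pass (28 lower adjusted over the list alone; median -0.94), and without the library labelled wild type TAC replicate 1 the number lower was 22 (median -1.09). Examples were Col14a1 (-1.43, SE 0.26) and Thbs2 (-1.05, SE 0.2). Camera gave the list an adjusted p of 1.8e-12, and an adjusted p = 0.44 with an estimated correlation. Col1a1, at -1.14 (SE 0.42, adjusted p = 0.099), Col3a1, at -0.94 (SE 0.36, adjusted p = 0.11), and Postn, at -1.48 (SE 0.49, adjusted p = 0.079), did not pass. The matrix score was 6.35 ± 0.48 in knockout (n = 4) and 7.18 ± 0.72 in wild type (n = 6; exact two-sided permutation p = 0.081), with an exact p = 0.04 without the library labelled wild type TAC replicate 1.

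Among 28 genes of TGF-beta signalling 8 were lower and 1 higher (17 and 1 without the library labelled wild type TAC replicate 1; 15 lower and 1 higher adjusted over the list alone; median -0.36; camera adjusted p = 6.7e-06; adjusted p = 0.41 with an estimated correlation). The receptor gene Tgfbr2 was lower (-0.5, SE 0.09), and Id1, a target of bone morphogenetic protein signals, was higher (0.58, SE 0.13), a call lost without knockout TAC replicate 2, 4 or 5. Among 23 pan-macrophage genes 5 were lower (12 without that library; 13 lower and 1 higher adjusted over the list alone; median -0.49; camera adjusted p = 8.1e-06; adjusted p = 0.44 with an estimated correlation). They included Adgre1 (-0.71, SE 0.17; 14.5 ± 3.53 CPM in wild type TAC, n = 6, and 8.9 ± 1.62 CPM in knockout TAC, n = 4), whose adjusted p was 0.077 without knockout TAC replicate 4 and 0.068 without replicate 5. Of 16 resident-type macrophage genes 3 were lower (6 without that library; 4 adjusted over the list alone; median -0.26), among them the scavenger receptor gene Cd163 (-0.79, SE 0.15) and Mrc1 (-0.6, SE 0.13; call lost without knockout TAC replicate 5). Their camera adjusted p was 0.0016, with an adjusted p = 0.41 with an estimated correlation.

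**Figure D4:**
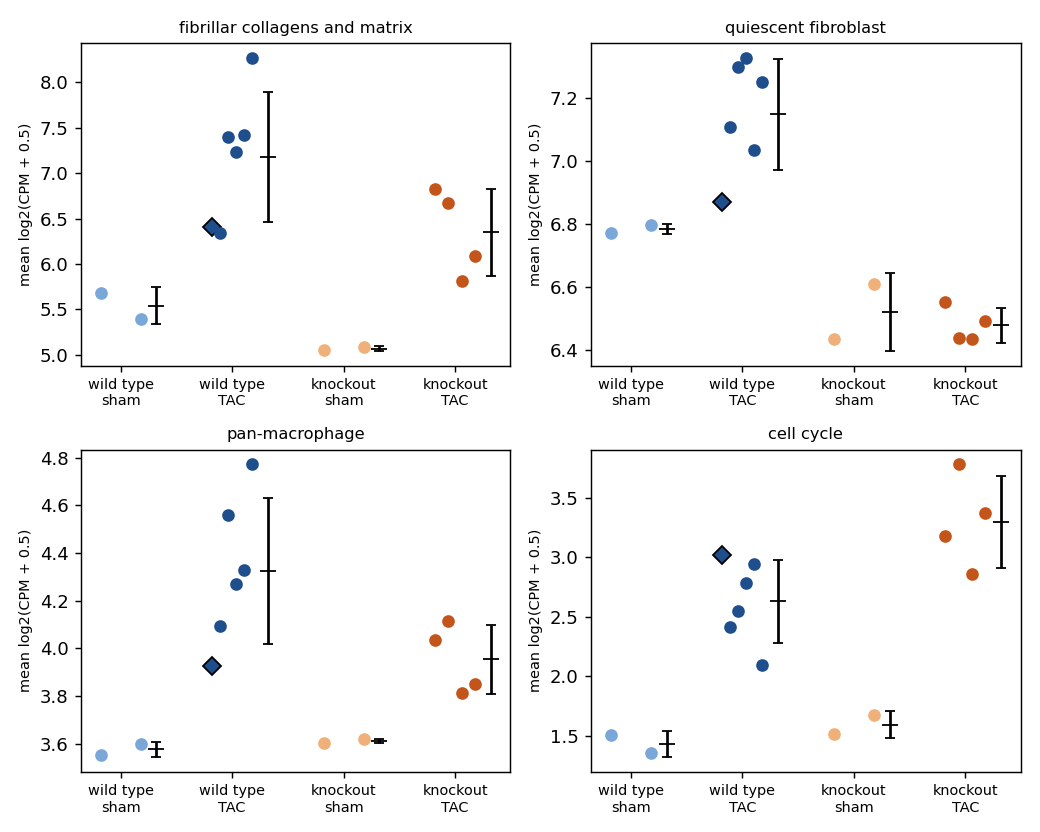
Scores of 4 gene lists, each the mean of log2(CPM + 0.5) over the members (vertical axes), in each library, by group (horizontal axes). Points are libraries, black bars are the mean ± SD of a group and the diamond is the library labelled wild type TAC replicate 1. After TAC the quiescent fibroblast score was 6.48 ± 0.06 in knockout and 7.15 ± 0.18 in wild type.

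Among 31 cell cycle genes 15 were higher in the knockout after TAC (26 adjusted over the list alone; median 0.82; camera adjusted p = 1.3e-14; adjusted p = 0.41 with an estimated correlation). They included Mki67, a marker of cycling cells (1.04, SE 0.22), whose adjusted p was 0.059 without knockout TAC replicate 5. Of 37 nuclear-encoded respiratory chain genes 15 were higher (31 without the library labelled wild type TAC replicate 1; 30 adjusted over the list alone; median 0.35; camera adjusted p = 5.1e-16; adjusted p = 0.41 with an estimated correlation), for example Cox5a (0.45, SE 0.1), whose adjusted p was 0.066 without knockout TAC replicate 4 and 0.067 without replicate 5. The share of mitochondrially encoded counts was also higher in knockout TAC, at 16.5% ± 1.92 (n = 4), than in wild type TAC, at 13.9% ± 2.79 (n = 6). Of 26 immediate early genes 11 were higher and 1 lower (12 and 1 adjusted over the list alone; median 0.34; camera adjusted p = 2.4e-08; adjusted p = 0.41 with an estimated correlation), among them Jun (0.56, SE 0.08), Dusp1 (0.95, SE 0.13) and Fosb (2.3, SE 0.39). Of 21 endothelial genes 3 were higher and 1 lower (6 and 1 without the library labelled wild type TAC replicate 1; 7 and 1 adjusted over the list alone; median 0.22; camera adjusted p = 0.0011; adjusted p = 0.47 with an estimated correlation). Their median was also 0.22 after sham surgery, where none passed. Load-induced cardiomyocyte genes were not called as a list (camera adjusted p = 0.19), with Nppb at 0.16 (SE 0.19, adjusted p = 0.63), Acta1 at -0.17 (SE 0.18, adjusted p = 0.55) and Nppa at -1.7 (SE 0.51, adjusted p = 0.059), and 1 of 25 was lower (0 adjusted over the list alone; median -0.24). The numbers were 4 lower and 1 higher without the library labelled wild type TAC replicate 1.

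**Figure D5:**
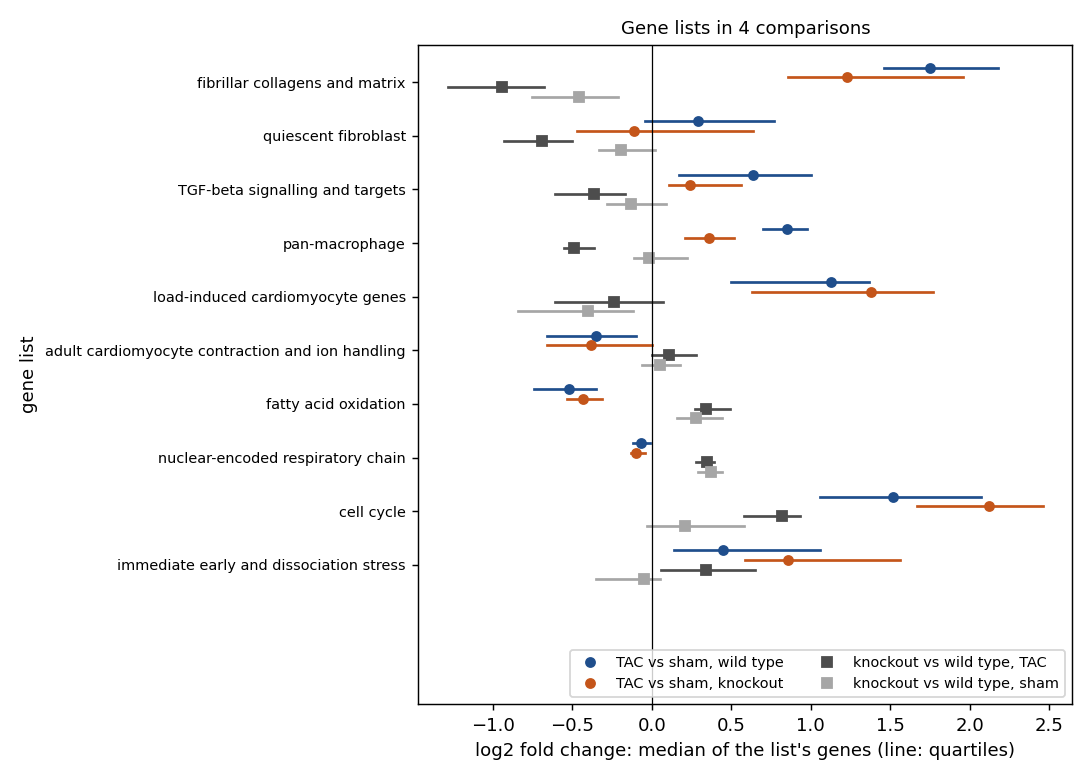
Median log2 fold change (horizontal axis) of the genes of 10 lists (vertical axis) in 4 comparisons, with lines from the lower to the upper quartile of the genes. Circles are TAC against sham and squares are knockout against wild type; matrix genes stood at medians of 1.75 and 1.23 after TAC and at -0.94 between genotypes after TAC.

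Between the genotypes after TAC 1483 genes were called, 589 higher and 894 lower in the knockout. Zhx2, a transcriptional repressor gene on chromosome 15, showed the largest difference per SE among the higher named genes, at 3.51 (SE 0.23; 22.7 ± 2.31 CPM in knockout TAC, n = 4, and 2.02 ± 1.01 CPM in wild type TAC, n = 6). Other large differences were in Myoc (-3.16, SE 0.54), Angptl7 (-2.8, SE 0.56; lost without knockout TAC replicate 2, 4 or 5) and Zbed5 on chromosome 5 (-2.39, SE 0.17). Gm49130, at 4.74 (SE 1.25), reached 30.2 CPM in knockout TAC replicate 5 and at most 0.8 CPM in the other knockout TAC libraries, and its call was lost in 11 of the 14 fits that left out a library, including the fit without that library. The count was 606, 451 and 302 without knockout TAC replicate 2, 4 or 5, 951 without wild type sham replicate 2, and 657, 669 and 972 without wild type TAC replicate 3, 4 or 6. It was 2939 without the library labelled wild type TAC replicate 1, including 1477 of the 1483. Of 49 named genes besides Ccl24 called here, 22 were called whichever library was left out, among them Pdgfra, Tcf21, Cd248, Dpt, Mmp2, Col14a1, Thbs2, Tgfbr2, Cd163, Jun, Dusp1, Fosb, Myoc, Zhx2 and Zbed5.

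Knockout against wild type after sham surgery asked how the genotypes differed without pressure overload. With edgeR over all libraries 6 genes were higher and 14 lower in the knockout, while DESeq2 called 140, limma voom 705 and edgeR on the 2 sham groups alone 1158. Zhx2 was higher (4.33, SE 0.41), at 25.8 ± 3.29 CPM against 1.27 ± 0.074 CPM (SD, n = 2 each), as were Fabp7, a fatty acid binding protein gene (4.35, SE 0.76; 1.05 ± 0.0352 CPM against 0.0467 ± 0.00571 CPM, the latter below the level of 3 counts), and the chemokine gene Cxcl14 (2.09, SE 0.31). Zbed5 (-2.31, SE 0.25), Mfap1a, a splicing factor gene with the close copy Mfap1b (-1.83, SE 0.27), and Arl2bp (-1.59, SE 0.19) were lower.

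No member of the matrix list passed after sham surgery (0 adjusted over the list alone; median -0.46; camera adjusted p = 0.0015; adjusted p = 0.82 with an estimated correlation). Quiescent fibroblast genes had a median of -0.19, with 0 passing and 1 lower adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.53 with an estimated correlation). Respiratory chain genes had a median of 0.37 with none passing in either count (camera adjusted p = 1.4e-14; adjusted p = 0.53 with an estimated correlation), beside a mitochondrially encoded share of 22.1% ± 2.26 in knockout sham and 18.6% ± 0.212 in wild type sham (n = 2 each). Pan-macrophage genes had a median of -0.02, none passed in either count and camera did not call them (adjusted p = 0.98). Postn, at -1.74 (SE 0.75, adjusted p = 0.42), and Nppa, at -1.7 (SE 0.77, adjusted p = 0.44), did not pass. The load-induced cardiomyocyte score was lower in knockout sham (7.06 and 7.01) than in wild type sham (7.56 and 7.45). In the fit without the library labelled wild type TAC replicate 1 that list had a median of -0.4 and 0 passing (camera adjusted p = 0.00022; adjusted p = 0.62 with an estimated correlation). The count of 20 genes was 8 and 3 without knockout sham replicate 1 or 2, 4 without either wild type sham replicate, 31 without knockout TAC replicate 1, 79 without wild type TAC replicate 7, and 63 without the library labelled wild type TAC replicate 1, and only Zhx2 and Zbed5 among the 16 named genes called here were called in all of these fits. Of the 1483 genes called after TAC, 1350 (91%) had the same sign after sham surgery, and these comparisons share no library.

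The interaction asked whether the effect of TAC itself differed between the genotypes. No gene passed with edgeR, 647 had an unadjusted p under 0.05, DESeq2 called 6 and limma voom called 5. The smallest unadjusted p-values belonged to Sik1 (1.1, SE 0.17, adjusted p = 0.11) and Apold1 (1.65, SE 0.27, adjusted p = 0.11), a gene of activated endothelium, on the higher side, and to Cd163 (-1.4, SE 0.27, adjusted p = 0.35) and H19 (-1.32, SE 0.28, adjusted p = 0.7) on the lower side. Mean Cd163 was 11.3 ± 0.302 CPM in wild type sham (SD, n = 2), 17.5 ± 3.7 CPM in wild type TAC (n = 6), 17.2 ± 2.57 CPM in knockout sham (n = 2) and 10.1 ± 0.338 CPM in knockout TAC (n = 4). Col1a1 (-0.54, SE 0.74), Col3a1 (-0.68, SE 0.64) and Postn (0.25, SE 0.87) had an adjusted p of 1 each, so the larger number of matrix genes past the threshold in wild type is not shown to be a difference between genotypes. Without the library labelled wild type TAC replicate 1 edgeR called 3 genes, Apold1 (1.78), Cd163 (-1.5) and Casq1 (1.01), the last of which was named after its value was seen. The count was 1 without knockout TAC replicate 4 and 1 without wild type TAC replicate 7.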

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

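In this part the tests of neighbouring genes and of a carried chromosome segment were set before their results were seen. The list tests with camera and fry and the fits that left out a library were planned, but their use to weigh an explanation came afterwards. The other tests were chosen only after the result was seen.

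The library labelled wild type TAC replicate 1 held Ccl24 at the knockout level and lay between the ranges of the genotypes at 13 of 18 other separating genes. A knockout library under a wild type label is argued against as the whole account, because the library lay on the wild type side of the knockout range at 83.3% of these genes, above the highest share of a left-out knockout library (58.1%). A mixture of wild type and knockout RNA is argued against only narrowly. With the best single share of knockout RNA (0.56) the mean squared deviation of Ccl24 and the 18 genes, in units of the spread between animals, was 6.72, where the 13 other libraries gave 0.956 to 5.47 when left out. An animal of mixed genetic background without Ccl24 may account for both and stays open. The 18 genes gave 2 neighbouring pairs within 20 Mb, so a wider set of 115 genes was tested, with a gap between the genotypes of at least 0.2 of the mean difference in place of 0.5, and neighbours did not share positions beyond the threshold (74 pairs, mean difference 0.335, permuted median 0.38, one-sided permutation p = 0.054). No source used here gives the genotyping or the breeding, so the library was left under its label.

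After TAC 15 of 21 quiescent fibroblast genes and 7 of 39 matrix genes were lower in knockout than in wild type, and neither list was called with an estimated correlation (adjusted p = 0.058 and 0.44; exact p = 0.081 for the matrix score). Without the library labelled wild type TAC replicate 1 the matrix median was -1.09, so the matrix difference did not come from that library. Its matrix score (6.41) lay near the knockout TAC mean (6.35), so leaving it out was bound to widen the gap. Wild type TAC replicate 2 (6.34) also lay below knockout TAC replicates 1 and 2 (6.82 and 6.67). Wild type TAC replicates 3, 4, 6 and 7 lay at 7.2 to 8.3. A lower level of load genes after TAC as the whole cause was weighed by the genotype difference with the load-gene score in the model. That model takes the load score as free of error. For the quiescent fibroblast score the difference was -0.6 (SE 0.09, exact p = 0.0048), with a slope of 0.25 on the load score. This argues against that cause for these genes. For the matrix score it was -0.35 (SE 0.15, exact p = 0.048, n = 10 libraries), with a slope of 1.73. This narrow result cannot decide, since error in the load score would leave part of a load effect in the difference. The form of this test tried first, matrix minus load score, gave -0.55 (exact p = 0.033). With the load score in the model, the permutation takes the labels as independent of that score. The score is a level, not a rise from sham, and was already lower in knockout sham (7.06 and 7.01) than in wild type sham (7.56 and 7.45). As a rise from sham, load genes were not lower in the knockout (median interaction 0.18), but that list was not called with an estimated correlation. A difference present before surgery could not be told apart for the matrix genes. Their median was -0.46 after sham surgery and the median interaction was -0.48, with adjusted p = 0.81 with an estimated correlation. For the quiescent fibroblast genes camera called the interaction with the preset correlation, but not with an estimated one, and fry did not call it. Without the library labelled wild type TAC replicate 1 the adjusted p with an estimated correlation was 0.11. A difference before surgery could therefore not be told apart for these genes either. Their score was already lower in knockout sham (6.43 and 6.61) than in wild type sham (6.77 and 6.8), and their median interaction was -0.53. An effect of the missing chemokine, which the design names, and a difference in genetic background between the lines also stay open and were not separated. The time of tissue collection is not given, and clock genes differed between the genotypes, so it was not separated either. The numbers that end the sample titles were all lower for knockout than for wild type libraries. What these numbers stand for is not given.

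Among the genes that set the 6 knockout libraries apart, a chromosome segment carried along with the Ccl24 deletion may account for the nearest ones. Of the 18 genes, 2 (Zbed5 and Mrps17) lay within 10 Mb of Ccl24, or 11.1%, against 1.42% of tested genes (Fisher's exact test, two-sided p = 0.027). These 2 are close neighbours, starting at 129895723 and 129715497 on chromosome 5. The test takes genes as independent, so its p-value may count a single place as 2. A carried segment of that size is argued against for the other 16, which with these 2 lay on 11 chromosomes, and genes called after TAC were not enriched near Ccl24 (21 of 1480, Fisher's exact p = 1). No biological explanation of the distant genes was tested.

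From 210 splits of the 10 TAC libraries into 4 and 6, 100 were drawn, with the real split included. Of these, 3 called at least 1483 genes, the real split among them, a share below 0.05 for the splits drawn. The other splits were not run and the test was chosen after the result was seen, so chance is not excluded. The highest other split called 3340 genes and set wild type TAC replicates 3, 4, 6 and 7 against all other TAC libraries, and the next called 2239 and set 3 knockouts with the library labelled wild type TAC replicate 1 against the rest. The former also put wild type TAC replicate 2 with the knockouts. Counts above the real one point to a structure of the samples besides their labels, whose nature was not tested.

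A library far from the others of its group was found in 20 of 332 group-wise tests of the named genes and list scores (6.02%), where chance gives about 1 in 20. The numbers that follow are the gap to the nearest library as a share of the range of the group. In wild type TAC the library labelled replicate 1 was apart at Arl2bp (0.702), Cd36 (0.713), Cd68 (0.709), Sgo1 (0.663) and Zfp979 (0.636), replicate 2 at Cks2 (0.785), Gm10254 (0.634) and Gm40604 (0.639), replicate 6 at Dlgap5 (0.755), and replicate 7 at Gcnt4 (0.667), Serpina3g (0.642) and Thbs4 (0.681). In knockout TAC replicate 1 was apart at H2-Q5 (0.854), Id1 (0.895), Krt18 (0.86) and Nr4a1 (0.839), replicate 4 at Ky (0.887), Ska1 (0.872) and Slc38a5 (0.841), and replicate 5 at Gm49130 (0.987).

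The effect of TAC differed between the genotypes for 12 gene lists by camera's test of the interaction with the preset correlation, and for 0 of 39 with an estimated correlation (adjusted p of 0.16 to 0.81 among the 12), and fry called 0. The median interaction was -0.48 for the matrix list, -0.53 for quiescent fibroblast, -0.22 for TGF-beta signalling, -0.47 for pan-macrophage, -0.23 for resident-type macrophage, -0.58 for MHC class II and -1.6 for neutrophil genes. It was 0.18 for load-induced, 0.48 for cell cycle, 0.43 for immediate early, 0.99 for epicardial and mesothelial and 1 for red blood cell genes.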

How the results depend on the processing

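All alternatives here were planned. RLE and upper-quartile scaling, the stricter filter, non-robust fitting and removal of mitochondrial and haemoglobin genes kept the total of called genes in every comparison within 1.5 times (genes lower after sham went from 14 to 22 with RLE), and leaving out a library kept every count of called lists within it. Counts below are in the order TAC in wild type, TAC in knockout, genotype after TAC, genotype after sham and interaction, where edgeR with all libraries gave 1930, 648, 1483, 20 and 0. DESeq2 gave 2774, 1319, 2317, 140 and 6, and limma voom 5730, 1898, 4587, 705 and 5. With the 2 compared groups alone the first 4 were 736, 1458, 783 and 1158. Without a filter the last 2 were 44 and 3. Leaving out 1 library gave 0 to 2756, 1 to 1361, 302 to 2939, 3 to 79 and 0 to 3; with 1 sham library left, that library is assumed to vary like the other groups. The labels do not say that the replicate numbers pair the mice. Libraries with the same number correlated at -0.22 to 0.06 in their deviations from the group mean. This cannot exclude pairing, because in a group of 2 the deviations mirror each other. With the replicate block the counts were 22, 367, 45, 13 and 0. Wild type TAC replicates 3, 6 and 7 and knockout TAC replicate 5 have numbers that no other library has. The block therefore fits each of them exactly, and they add nothing to the comparisons. The lower counts cannot be read as an effect of pairing. Lists called were 17, 18, 16, 13 and 12; with an estimated correlation 0, 1, 0, 0 and 0; with fry 18, 7, 11, 0 and 0. The correlation of TAC responses was 0.64, 0.76 with the stricter filter and 0.47 to 0.66 without 1 library. Apart from fewer genes or libraries, the cause of these shifts was not tested.

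Ccl24 in TAC against sham in knockout turned to -0.15 with the replicate block and -0.04 with voom, and its leave-one-out range was -0.34 to 0.71. The range was -0.43 to 0.05 for TAC in wild type, -0.13 to 0.91 for the interaction and -4.37 to -3.32 after sham surgery. After TAC it was -3.12 and did not pass with the block (adjusted p = 0.32), where fewer libraries inform the comparison. After sham it passed with the 2 groups alone (-3.74) and with DESeq2 (-3.8). None of the named genes that turned sign had passed. For the Nppa interaction (0) the values were 0.01 with RLE, without a filter, without mitochondrial and haemoglobin genes and with DESeq2, 0 with upper-quartile scaling and 0.91 with the block (-0.28 to 0.35 without 1 library). The block also turned the interactions of Myh7 (0.07), Col1a1 (0.35) and Col3a1 (0.04) and, after TAC, Myh6 (-0.1), Myh7 (0.03) and Acta1 (0.08), and voom turned Myh6 after TAC (-0.04). Ranges without 1 library were -0.04 to 0.11 for Myh6, -0.13 to 0.06 for Myh7 and -0.01 to 0.31 for Nppb between genotypes after TAC. After sham they were -0.07 to 0.2 for Myh6, -0.19 to 0.16 for Myh7 and -0.16 to 0.09 for Adgre1, and for the interaction -0.16 to 0.11 for Myh6, -0.21 to 0.14 for Myh7 and 0 to 0.6 for Postn. A sex covariate was not run, since all libraries held Y-linked counts and at most 3 Xist counts. At 3 counts per library, levels below 0.091 to 0.18 CPM are not resolved.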

Other observations

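No explanation was tested in this part, and the clock genes were chosen only after a difference at some of them had been seen. After sham surgery Arntl, which codes for the clock activator BMAL1, stood at 3.09 (SE 0.65) in knockout against wild type, and Dbp at -1.74 (SE 0.32), Per2 at -1.57 (SE 0.51) and Cry2 at -0.94 (SE 0.18). Of 11 genes that peak with the PER repressors all 11 were below 0 (median -1.2), and of 5 genes that peak with BMAL1 4 were above 0 (median 0.93), but none passed (n = 2 against 2). After TAC 4 of the 11 were lower past the threshold (median -0.56), among them Cry2 (-0.63, SE 0.12) and Bhlhe41 (-0.65, SE 0.14), and Per1 (0.15, SE 0.19) and Ciart (0.34, SE 0.26) were above 0 without passing. Of the 5 genes that peak with BMAL1 only 2 passed, in opposite directions, Arntl at 1.33 (SE 0.38, adjusted p = 0.046) and Cry1 at -0.82 (SE 0.18, adjusted p = 0.013). The time of tissue collection is not given in the sources used here.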
